A study of Mus musculus with 16 samples.

How the data were processed

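The data are 16 two-colour oligonucleotide arrays on tail DNA of 8 mice, 2 parents and 6 progeny, each animal hybridised in both dye orientations against 1 male reference mouse. Per the labels' protocols, DNA was extracted by a commercial protocol for tissue DNA and labelled by the array maker's protocol for genomic DNA. Per the file headers, the scanner images were read with Feature Extraction 10.7.1.1 under the protocol CGH_107_Sep09, and probe positions are those of the mouse build mm9 (NCBI37). The processed red and green values that the authors deposited are intensities after background subtraction and linear dye normalisation, per the file headers, with no lowess step. Beside them stands the scanner's own log ratio, per the file headers the log10 of red over green, which was used only to check the signals. The deposited series table holds log2 ratios of the authors; regressed on the scanner ratios, its columns proved to be reference over family animal in every array, with slopes of 0.987 to 1 on log2 red over green where the family animal was in Cy3 and -0.991 to -0.979 where it was in Cy5. The medians of its columns lay between -0.01 and 0.02, and what centring the authors applied beyond that is not given in the sources used here. All signed values in the text run the other way, as family animal over reference.

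From the processed signals, the log2 ratio of family animal to reference was computed for each array, with control spots and spots flagged as outliers left out, spots of a probe averaged and each array centred on its autosomal median. No loess or quantile step was applied, since copy number differences may shift many probes. The 2 arrays of an animal carry the same pair of DNAs and were averaged to 1 value per probe; each animal counts once. Arrays of different animals in the same dye orientation correlated positively over 949716 probes (median r of 0.43 in Cy5 and 0.36 in Cy3) and the 2 arrays of an animal, turned to the same direction, negatively (-0.46 to -0.10), which is a probe-specific dye effect that the average of the orientations removes. After averaging, animals correlated at -0.13 to 0.42. The signal to noise ratio per channel ranged from 17.2 to 43.

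Regions were called per animal on the autosomes with an interval score, the sum of log2 ratios divided by the robust probe noise and the square root of the number of probes. The best interval of 3 to 1000 probes was taken repeatedly to the left and right of earlier ones and kept at a score of at least 6, a mean of at least 0.25 in size and at least 0.125 of the same sign in each dye orientation. Probe noise was 0.11 to 0.17 on the log2 scale. Calls of the same sign that overlapped between animals were merged and classed by carriers. A level given for a region is the mean over all its merged probes, which can be smaller in size than that of a call within it. The level expected by chance was taken from 20 shuffles of probe positions within chromosomes per animal. On shuffled probes of the female parent with 200 regions put in, the caller recovered 95.5% of losses of 3 probes at -0.5 and 54.5% of gains of 10 probes at 0.25; on those of progeny 4, a noisier animal, it recovered 23% and 15.5%, and 100% of regions of 10 probes at 0.5 in both.

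Counts per animal were compared by an exact two-sided permutation test. Probes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with Benjamini-Hochberg adjustment), with coefficients for 6 progeny and 2 parents. In that model 200 probes changed by 0.5 in all 8 simulated animals were recovered at 98.5% in the test of the family against the reference, with 27 false calls. Scan day was available for each array. There were 5 days, each with a single kind of animal, with both parents on 1 day and progeny on the other 4. The day was tried as a random block, whose correlation was estimated as -0.14 on 20000 probes. Because no day held both parents and progeny, this block cannot separate day from group. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and numba 0.67.0.

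The tests, the alternatives and the rule for named regions were fixed before the data were examined. By that rule the 10 regions with the highest interval score in any animal were named in each class of carriers, with a summary where they were alike, and up to 10 probes with the lowest adjusted p in the test of progeny against parents, which gave none. The alternatives were normexp background correction (offset 50), the series table, loess, other score, size and height thresholds, each dye orientation alone, removal of the 26886 autosomal probes that were dim, saturated or outliers on an array, the median of the 8 animals as baseline, a stricter overlap for merging, and leaving out each animal. Normexp was run on the median signals of the spots in place of the planned mean signals. A minimum of 10 probes, the smaller of the dye orientations, region counts without single progeny and the random block were added after the data were seen. The gene table at hand follows GRCm38, another build than that of the probes, so no gene was assigned to a region, and the planned test of gene lists, the naming of genes and the correction for GC content were not run. The denser arrays and quantitative PCR assays of the study were not analysed here.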

Results

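Array comparative genomic hybridisation was used to measure DNA copy number in tail tissue of a single mouse family of the strain C57BL/6JNrs. In this assay, DNA of an animal and DNA of a reference are labelled with different dyes and hybridised to the same array, and the ratio of the 2 signals at a probe follows the ratio of the copy numbers. The family consisted of a male parent, a female parent and 6 progeny, and each of the 8 animals was hybridised on 2 arrays with the dyes exchanged, which gave 16 arrays. The reference was DNA of 1 male mouse of the same colony on every array. The series belongs to a screen for copy number changes passed on by male mice kept under gamma rays at 0.05 mGy per day for 400 days. The title of the series places this family in the exposed arm, whereas the design text calls its male parent non-irradiated, so no exposure effect was assigned to the family. Each array carried 950749 distinct probes, of which 950622 lay on the 19 autosomes at a median spacing of 2053 bp. The median net signal of the family animal's channel ranged from 99.3 to 160 across the arrays, 0 probes were saturated, and at most 1.56% of probes were not well above background in a channel. The scanner's quality verdict was in range for all arrays of the parents and progeny 1. It asked for evaluation of both arrays of progeny 3, 4 and 6 and of the Cy5 arrays of progeny 2 and 5. The number of arrays per animal, 2, limits the precision of each value below, and errors on single animals are SDs over those 2 arrays.

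The sex chromosomes gave a known difference against which ratios were read. In the female parent the 68 X probes had a median log2 ratio of 0.90 ± 0.05 (SD, n = 2 arrays) to the male reference, and in the male parent 0.01 ± 0.03. The 23 Y probes had a median of -1.42 ± 0.11 in the female parent and -0.02 ± 0.05 in the male parent. Among the progeny, whose sex the labels do not give, progeny 1 had an X median of 0.02 ± 0.04 and a Y median of 0.04 ± 0.03, and progeny 2 to 6 had X medians between 0.87 and 0.90 and Y medians between -1.63 and -1.33. A doubling of X copy number, which is 1 on the log2 scale, was thus read as 0.90 in the female parent.

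**Figure D1:**
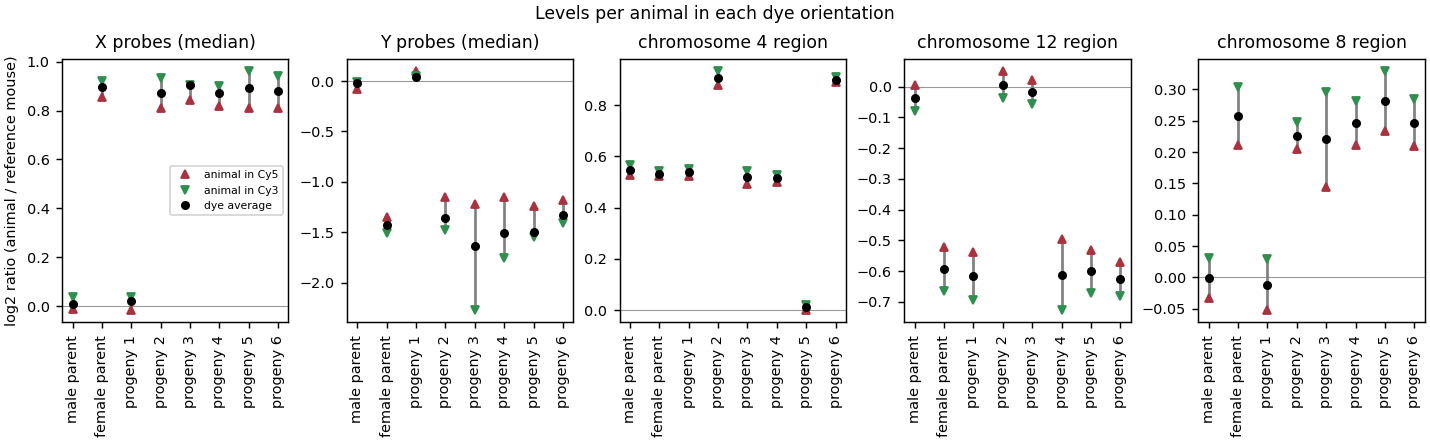
Log2 ratio of each animal to the reference mouse for X probes, Y probes and 3 autosomal regions, each panel with its own vertical scale; triangles are the 2 dye orientations and black dots the dye average. On chromosome 4 progeny 5 sits at 0.01, progeny 2 and 6 at 0.91 and 0.90, and the other 5 animals between 0.51 and 0.55.

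The longest region shared by parents and progeny was a gain of 163405 bp on chromosome 4, from position 101107131 to 101270535 of the mouse build mm9, covered by 75 probes and called in 7 of the 8 animals. The male parent was at a log2 ratio of 0.55 ± 0.03 and the female parent at 0.53 ± 0.01 (SD, n = 2 arrays each). Progeny 1, 3 and 4 lay at 0.54 ± 0.02, 0.52 ± 0.04 and 0.51 ± 0.02, the level of both parents. Progeny 2 and 6 lay higher, at 0.91 ± 0.04 and 0.90 ± 0.01, and progeny 5 was at 0.01 ± 0.01, level with the reference. These steps exceeded the spread between the dye orientations of every animal. The highest interval score of the region was 46.8, while the highest score of a call of 10 or more probes after shuffling probe positions was 11.8.

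A loss on chromosome 12 divided the family differently. It spanned 71303 bp, from 56184969 to 56256271, with 35 probes, and was called in 5 animals. These are the bounds of the merged calls, and the female parent's own call began at 56189969 with 34 probes. The female parent was at -0.59 ± 0.10, and progeny 1, 4, 5 and 6 were at -0.62 ± 0.11, -0.61 ± 0.16, -0.60 ± 0.10 and -0.63 ± 0.08. The male parent, progeny 2 and progeny 3 were at -0.04 ± 0.06, 0.01 ± 0.06 and -0.02 ± 0.05. The next probe beyond the distal edge began at 56368938. Past this gap the probes at 56383347, 56388242 and 56389506, chosen after their values were seen, were low in the same 5 animals. At 56389506 the female parent was at -0.59 and progeny 1, 4, 5 and 6 were between -0.70 and -0.68, against -0.10 to 0.00 in the other 3 animals. Between the gap and these probes the pattern was mixed. The 5 carriers lay between -0.20 and -0.04 at 56368938, between -0.34 and -0.02 at 56370465 against 0.03 to 0.56 in the other 3 animals, and between -0.23 and 0.13 at 56372683 and 56377225, so the distal end of the loss was not settled. Another long region, a gain of 130771 bp on chromosome 8 from 102122727 to 102253497 with 47 probes, was smaller in height. It was called in the female parent at 0.26 ± 0.07 and in progeny 2 to 6 at 0.22 to 0.28, and the male parent and progeny 1 were at 0.00 ± 0.04 and -0.01 ± 0.06. These values, means over all 47 probes, stood close to the minimum of 0.25 set for a call. Progeny 2, 3, 4 and 6 were under it, at 0.23, 0.22, 0.25 (0.247) and 0.25 (0.247), and their calls passed it over parts of the region. At a minimum of 0.40 the chromosome 8 region was called in 0 animals.

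**Figure D2:**
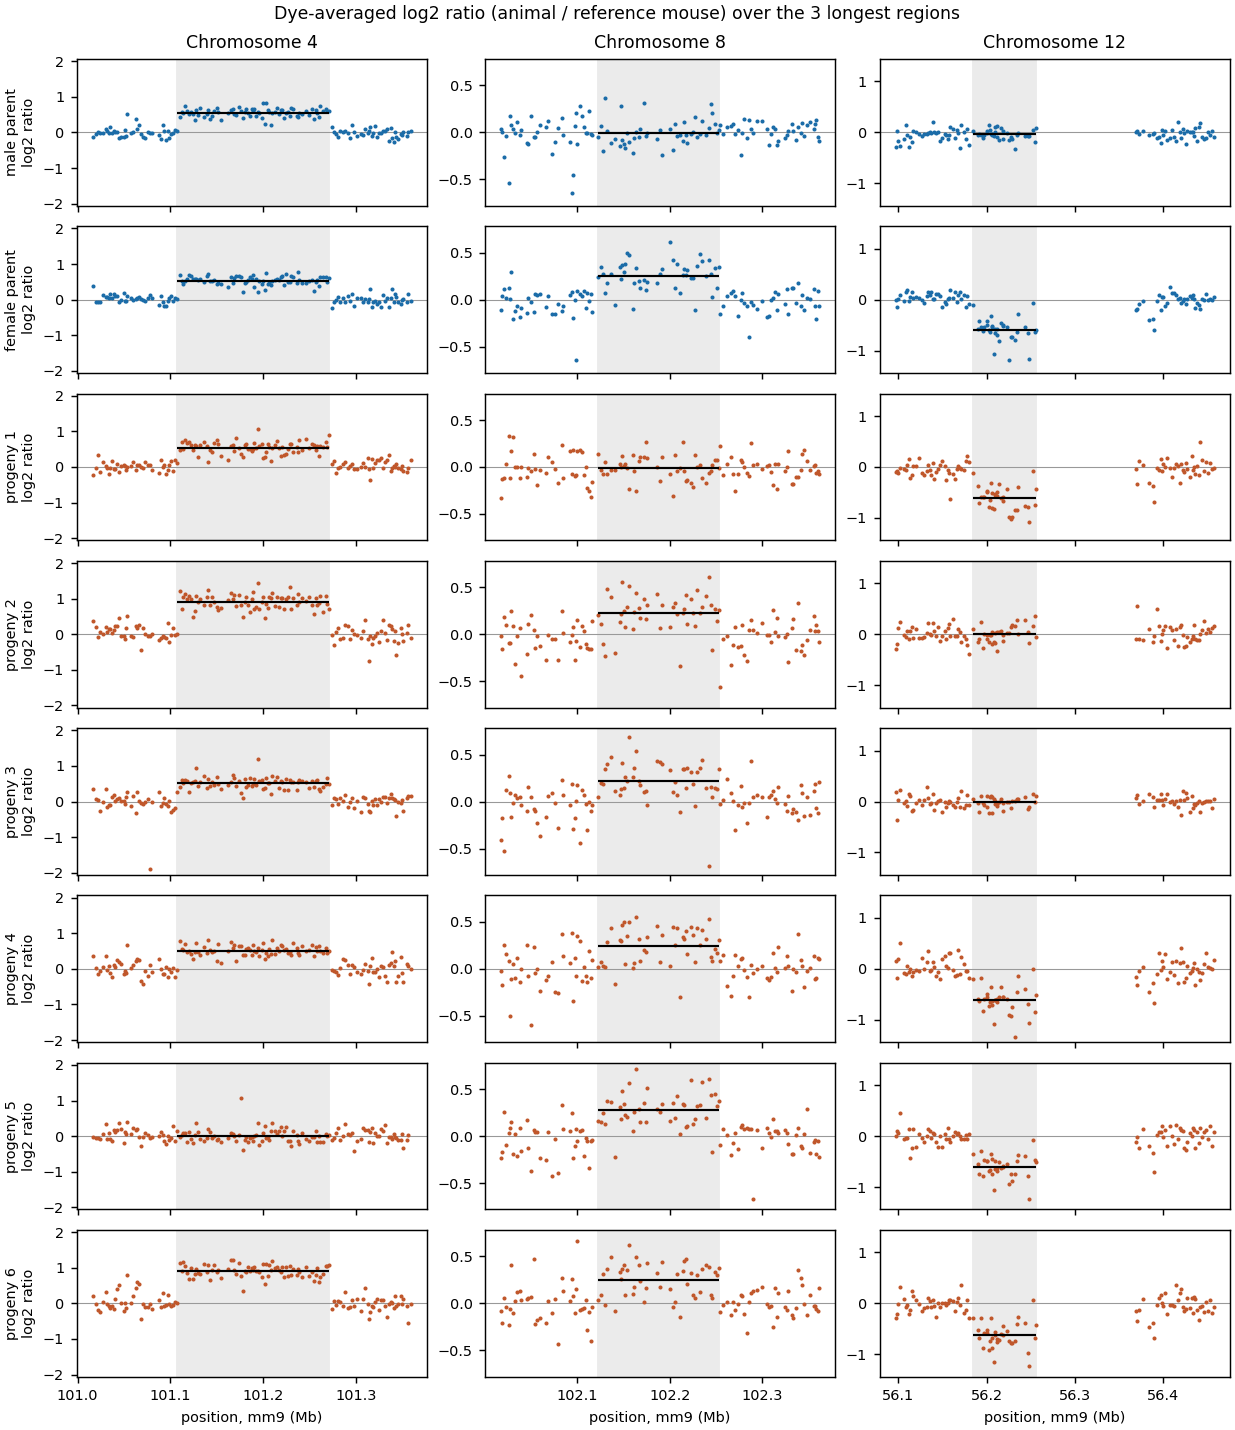
Dye-averaged log2 ratio of single probes, one dot each, against mm9 position for the 3 longest regions and their flanks in all 8 animals (blue parents, orange progeny); grey marks the region and the black line its mean. The chromosome 4 gain is present in 7 animals, the chromosome 8 gain in 6 and the chromosome 12 loss in 5.

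Altogether the calls of the 8 animals merged into 981 regions, of which 222 were gains and 759 losses. The screen was aimed at changes seen in progeny and in neither parent, and this class held 810 regions. A further 132 were seen in parents only, 39 in a parent and at least 1 progeny, and 0 in all 8 animals. With progeny 3 left out, the number of regions was 505, and 334 of them were in progeny only. Most merged regions, 922, were called in a single animal, and 898 consisted of 3 to 4 probes. Regions of 10 or more probes numbered 11, of which 5 were shared by a parent and progeny, 6 were in progeny only and 0 in parents only.

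Among the 39 regions shared by a parent and progeny, 1 set of animals recurred. The female parent and progeny 2 to 6 were the carriers of 11 regions on 9 chromosomes, 10 losses and the chromosome 8 gain, whereas the male parent and progeny 1 carried none of them. No other set of 4 or more animals was the full list of carriers for more than 2 regions. The 10 losses spanned 4 to 9 probes each after merging. The female parent's own calls in them held 3 probes each, or 4 in the deepest. The deepest, on chromosome 3 from 25417435 to 25444229 with 4 probes, was at -1.57 ± 0.01 in the female parent and between -1.64 and -1.48 in progeny 2 to 6, against 0.03 ± 0.01 in the male parent and 0.02 ± 0.13 in progeny 1. On chromosome 6 a loss of 5 probes from 104236953 to 104246570 was at -0.80 in the female parent and -0.02 in the male parent, on chromosome 7 one of 4 probes from 141015947 to 141020625 was at -0.81 and 0.00, and on chromosome 16 one of 5 probes from 40847733 to 40856111 was at -0.64 and -0.05. The remaining losses, a second one each on chromosomes 3 and 6 and one each on chromosomes 9, 10, 11 and 14, were between -0.49 and -0.28 in the female parent. These levels are means over the merged regions, and over the 3 probes of the female parent's own calls they were deeper. There the losses named above on chromosomes 6, 7 and 16 were at -1.43, -1.09 and -1.18, and the remaining ones between -0.99 and -0.58. The female parent and progeny 2 to 6 are the animals with raised X and lowered Y medians.

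**Figure D3:**
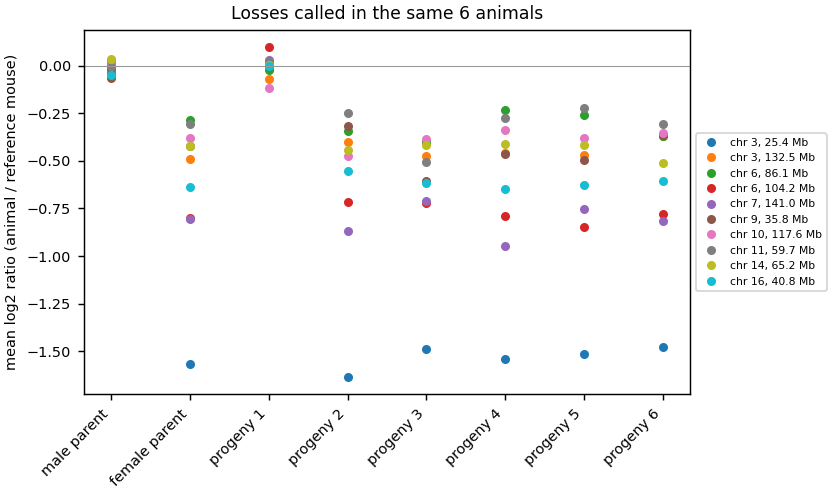
Mean log2 ratio of each animal to the reference mouse over the merged regions of the 10 losses called in the female parent and progeny 2 to 6. Each colour is a region, named by chromosome and mm9 start. The male parent and progeny 1 lie between -0.11 and 0.10 in all of them, and the chromosome 3 loss that starts at 25417435 reaches -1.64.

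Regions in progeny only came largely from 1 animal. Progeny 3 was the sole carrier of 476 of the 810, and all 10 with the highest interval score were losses of 3 to 5 probes in progeny 3. The highest, on chromosome 1 from 148422612 to 148426126 with a score of 21.3, was at -2.96 with progeny 3 in Cy5 and at -0.54 with progeny 3 in Cy3. The other 9 lay between -2.55 and -1.74 in the Cy5 orientation and between -0.25 and -0.16 in the Cy3 orientation, so their depth rested on the Cy5 array. On that array 7961 autosomal probes had a log2 ratio under -1, compared with 236 on the dye-exchanged array of the same DNA, and 24.1% of the 7961 lay in a single one of 60 equal blocks of the array surface. The Cy5 array of progeny 4 had such a block too, with 909 of its 3104 low probes, or 29.3%. Among progeny-only regions of 10 or more probes, a loss on chromosome 14 from 61798066 to 61819370, chosen after its values were seen, was called in progeny 2 to 5 at -0.35 to -0.28; the female parent was at -0.19 ± 0.01 and progeny 6 at -0.24 ± 0.04 without a call, and the male parent was at -0.07 ± 0.06 and progeny 1 at 0.02 ± 0.06. The animals with the lower levels were thus the female parent and progeny 2 to 6. The 10 highest-scoring regions in parents only had 3 probes each, scores of 8.92 to 10.4 and a single carrier, and 7 of them were losses. The first was a loss on chromosome 3 from 135558176 to 135561114 at -0.71 ± 0.22 in the male parent, and the next a gain on chromosome 15 from 94749403 to 94753975 at 0.66 ± 0.51 in the female parent. Another of the 10, a loss on chromosome 11 from 112955152 to 112961441, was not private to a parent by level. It was at -0.60 in the female parent and between -0.51 and -0.41 in progeny 2 to 6 without a call, against -0.05 in the male parent and -0.04 in progeny 1. To see how common this was, calls of the female parent were read in all animals, a comparison chosen after the values were seen. Of 97 calls in which the male parent had no call and stayed under 50% of the female parent's level, 43 on 17 chromosomes were past that level in progeny 2 to 6 and not in progeny 1, and 15 of the 43 had been classed as parents only. Outside the 11 shared regions the number was 32.

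**Figure D4:**
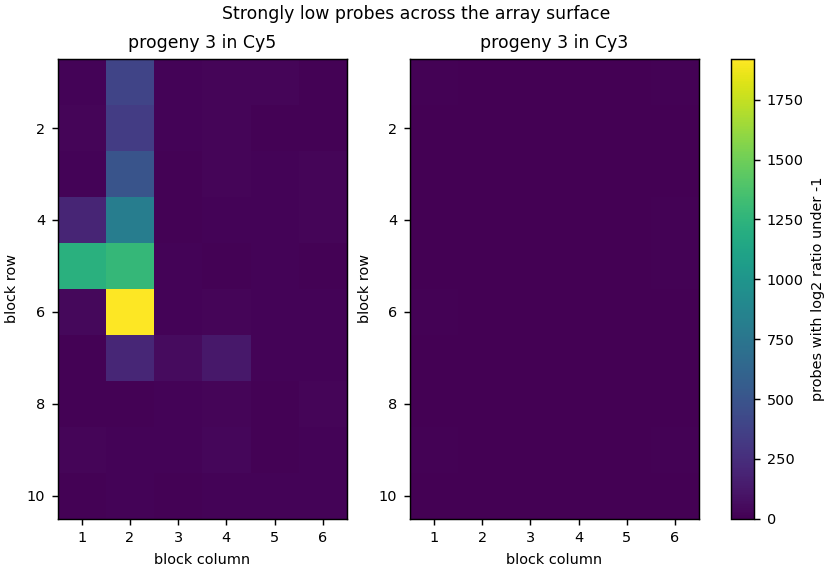
Number of autosomal probes with a log2 ratio under -1 in each of 60 blocks of the array surface, for the 2 arrays of progeny 3. The fullest block of the Cy5 array holds 1920 such probes, and the whole Cy3 array 236.

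Whether progeny held more regions than their parents was then asked of the counts per animal. The male parent had 68 regions and the female parent 106, and progeny 1 to 6 had 70, 60, 511, 153, 76 and 79. The score divides by probe noise, which was 0.12 in the male parent, 0.11 in the female parent and 0.14 to 0.17 in the progeny. A region of the same level and length thus scores lower in the progeny, and the parents were scanned on a day without progeny. The counts also depended on the background correction. With normexp the parents had 5 and 69 regions in the same order and progeny 1 to 6 had 18, 56, 761, 133, 44 and 53. Progeny averaged 158 ± 176 (SD, n = 6) and parents 87 ± 26.9 (SD, n = 2), and an exact two-sided permutation test over the 28 splits of the animals gave p = 0.679; the smallest p this design allows is 0.0357. Without progeny 3 the progeny mean was 87.6 ± 37.3 (n = 5) and the exact permutation p was 1. Shuffling the positions of probes within chromosomes, which breaks up regions of neighbouring probes, gave about as many calls as the real order. The 8 animals had 1123 calls in total, and 20 shuffles gave 1146 ± 29.1 (SD), with a range of 1081 to 1194. Calls of 3 to 4 probes numbered 1037 against 1084 ± 29.7 after shuffling, and those of 5 to 9 probes 60 against 54.7 ± 5.69. Only calls of 10 or more probes stood above the shuffled range, at 26 against 7.1 ± 2.53 and at most 12. Of these 26 calls, 18 were those of the chromosome 4, 8 and 12 regions, and the other 8, in progeny-only regions or elsewhere, were about as many as the shuffled mean. A single strongly deviating probe can bring 3 probes past the score wherever it lies, so these counts do not tell short regions from such probes.

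**Figure D5:**
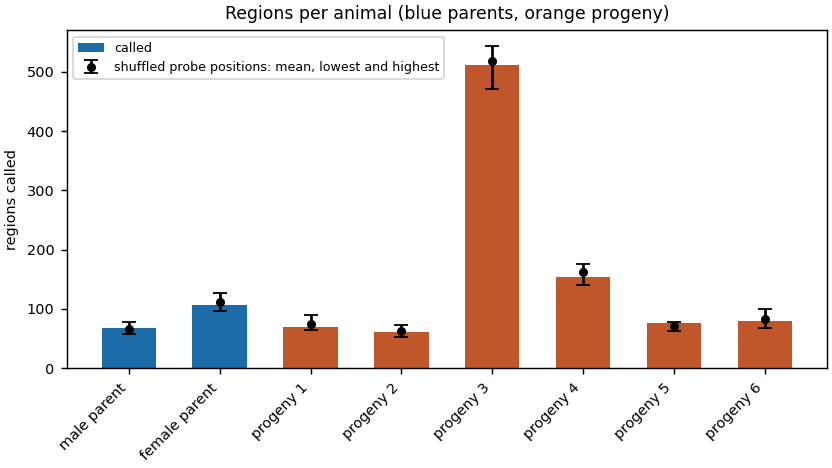
Regions called per animal (bars, blue parents, orange progeny) beside the mean and the lowest to highest number over 20 shuffles of probe positions (dots and error bars). In progeny 3 the 511 calls lie within the shuffled range of 471 to 543.

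At the level of single probes, progeny were set against parents with limma on the dye-averaged ratios of 949716 autosomal probes. At an adjusted p threshold of 0.05, 0 probes differed, the lowest adjusted p was 0.336, and 61030 probes had an unadjusted p under 0.05. Data were simulated with each probe's fitted spread and no correlation between animals. There this test recovered 98.5% of 200 probes changed by 1 on the log2 scale in all progeny, with 25 false calls. Of 200 probes changed by 0.5 it recovered 0.5%, with 3 false calls. Changes in only some of the progeny were not simulated, so the recovery does not apply to them. Leaving out the male parent gave 2 probes and leaving out the female parent 0, but the parents are then 1 animal and the spread comes from the progeny alone. The parents shared a scan day and no progeny was scanned on it, so day and group cannot be separated. With scan day as a random block, which does not remove this, the number was 0.

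Probes at which the family as a whole departed from the reference mouse were sought with the same model, as the mean of the 8 animals against 0. Because the reference is 1 mouse, this leaves out the spread of reference animals. There were 6607 probes with an adjusted p under 0.05 and a mean log2 ratio of at least 0.25 in size, 4558 higher and 2049 lower in the family. Of these, 72 lay in the chromosome 4 gain, 15 in the chromosome 12 loss and 9 in the chromosome 8 gain. Only 129 of the 6607, or 1.95%, had a neighbouring probe called in the same direction, so that nearly all were isolated probes. The number rested on single animals. It was 4, 7, 229 and 2 without progeny 2, 4, 5 and 6, 3496 without progeny 3 and 14179 without progeny 1.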

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

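Of the tests in this part, all but the removal of a single array block were chosen after the results they bear on, or closely related counts, had been seen, and the tests of inheritance and scan day on the shared regions were recast more than once after that. Of 9 measures examined over the 6 progeny, 5 had an animal far from the rest; chance alone marks about 1 group in 20, and the measures are related to each other. Progeny 3 stood apart with 511 regions and 489 losses, and progeny 1 with a median log2 ratio of 0.021 on X and 0.043 on Y and a chromosome 8 level of -0.012. On X and Y, progeny 1 was at the level of the male parent (0.01 and -0.02). Progeny 2 to 6 were near the female parent (0.90 and -1.42). By these values progeny 1 read as male and progeny 2 to 6 as female, so its X and Y flags reflect sex.

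The excess of losses in progeny 3 was set against the surface of its arrays. Of the probes under -1 on either of its arrays, 97.1% were so on the Cy5 array alone, whereas a deletion in the DNA would be low on both. In every other animal, too, more probes were under -1 on the Cy5 array than on the Cy3 array. The female parent had 1031 against 163 and progeny 4 had 3104 against 543, so an excess on that array is not particular to progeny 3, where it was largest. Leaving out the fullest block of that array left 350 calls, so that block alone was not the whole source, whereas leaving out the 4 blocks with over 5 times the even share, which hold 6.66% of probes, left 143. This is below the 153 of progeny 4, whose Cy5 array also has 29.3% of its low probes in 1 block, but above the 106 of the next animal. A streak on the Cy5 array is thus a likely source of most of these losses. The 4 blocks held 65.7% of the low probes of that array, and blocks that were kept held up to 502 each. The 143 calls were thus made with such blocks still in place, and why they remain was not tested.

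The low chromosome 8 level of progeny 1 belongs with the 11 regions called in the female parent and progeny 2 to 6 and in no other animal. Separate inheritance of autosomal variants is argued against, since of 60 regions picked by the parents alone, outside these 11, in which at least 1 progeny was past 50% of the female parent's level, 32 on 13 chromosomes had progeny 2 to 6 and not progeny 1 there and the next most common set of progeny had 5. For scan day, the parents, scanned on 1 day, and progeny 1 and 2, scanned on another, were compared over the 11 regions. They differed by medians of 0.45 and 0.36, against a median SD of 0.058 between the arrays of these animals. In 10 of the 11 both pairs differed by over 2 pooled SDs. These regions were picked for setting such animals apart. The differences were thus largely fixed in advance and cannot decide on scan day. Another form of the test used 18 regions picked by the progeny alone outside the 11. It had not settled the question, with a median of 0.31 between the parents and the female parent further out in 14. Signal from sequence that the probes share with the X or Y chromosome may account for the pattern. Its carriers are the animals with an X median near 0.90 and a Y median between -1.63 and -1.33. By direction, a higher X signal would go with the chromosome 8 gain and a lower Y signal with the 10 losses. Outside the called regions, 0 of the other 27 pairs of animals had as many 3-probe windows setting them apart as the male parent and progeny 1. The lead was only 1198 to 1192. Of windows that were higher in the other 6 animals 0 pairs had as many, at 943 against at most 913, while of lower ones, the direction of 10 of the 11 regions, 7 pairs had as many, so this test left the question open, and no genome sequence was at hand to search for shared sequence.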

How the results depend on the processing

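The minimum of 10 probes, the smaller of the dye orientations and the region counts without single progeny were chosen after the data were seen. The exact p of progeny against parents in region counts stayed above 0.05 under all 20 alternatives (0.0714 to 1), with progeny higher in each. The number of probes between progeny and parents was 0 with normexp, the series table, loess and removal of dim, saturated or outlier probes. It was 0 to 2 with single animals left out, and other signal choices were not run for that test. The chromosome 4 gain and the chromosome 12 loss were called in 7 and 5 animals under every alternative run for them but the median of the 8 animals as baseline, which by construction moves carriers to 0 and gave 2 and 0. The chromosome 8 gain was called in 6 animals, but in 0 with that baseline, 0 at a minimum mean of 0.40, 0 with the smaller orientation, 1 in the Cy5 and 4 in the Cy3 orientation alone, 4 with normexp and 5 with loess. Of 144 levels of the 3 regions per animal under other signals, 137 moved by less than the SD of the arrays and 0 reversed. These signals included each dye orientation alone, which lies within that SD of the average by construction. Reversal was counted only in called animals.

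Counts of regions changed by over 1.5 times under some choices and by less under others. Under the series table, loess, a minimum mean of 0.15 or 0.40, the median baseline and the stricter overlap, total calls, merged regions and the classes stayed within 1.5 times of the main values. Total calls, merged regions and the classes parent and progeny, parents only and progeny only, which were 1123, 981, 39, 132 and 810, became 2876, 2517, 83, 382 and 2052 at a score of 5, 354, 294, 14, 28 and 252 at a score of 8, 565, 482, 22, 60 and 400 with at least 5 probes, and 142, 101, 9, 2 and 90 with at least 10. The Cy5 orientation alone gave 3001, 2919, 18, 67 and 2834. The Cy3 orientation alone gave 530 calls, 452 merged regions, 83 in parents only and 340 in progeny only. Without dim or outlier probes there were 738 calls, 617 merged regions and 46 in parents only, and normexp gave 31 in parents only at a total of 1139 calls. Counts of single animals moved more, as normexp gave 5, 69, 18 and 44 in the male parent, the female parent, progeny 1 and progeny 5, and the median baseline 148 in the male parent and 107 in progeny 1. The smaller orientation gave 6498 calls, 5437 merged regions, 82 shared by a parent and progeny, 5170 in progeny only and 1 in all animals. Thresholds change these counts by construction; for the other settings the cause was not tested.

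Leaving out single progeny gave 612 to 1063 calls, 505 to 943 merged regions, 334 to 772 in progeny only and 0 to 1 in all animals; the lowest are without progeny 3, and the 1 is the chromosome 4 gain without progeny 5. The number of probes between family and reference was 2 to 14179 without single animals and 4106 with normexp. The GC correction and the gene list tests were not run. Of the long regions, the chromosome 4 gain and the chromosome 12 loss kept their number of called animals under the normexp background correction, while the chromosome 8 gain had 2 fewer. Probe noise limited regions of few probes at a log2 ratio of 0.5 or less.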

Other observations

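The tests in this part were chosen after the values had been seen. The levels of the chromosome 4 gain fall into separate steps, and a candidate explanation is a segment present in whole numbers of extra copies that segregates in the family. With 2 copies in the reference and ratios scaled by the X median of the female parent, 1 and 2 extra copies would be read as 0.53 and 0.90, and the animal farthest from the nearest of 0, 0.53 and 0.90 was off by 0.023. Dye bias is argued against, since the lowest value of a called animal in either orientation was 0.49, and scan day is argued against by a difference of 0.89 between progeny 5 and 6, which were scanned on the same day. Under this reading both parents would carry 1 extra copy and the progeny 1, 2, 1, 1, 0 and 2 in order of their numbers, with no level in the progeny that the parents could not pass on. The reading was found on the same data and remains a hypothesis, and a different copy number in the reference would shift it.

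The other long regions do not fall on such steps. The chromosome 12 loss, at -0.63 to -0.59 in its carriers, was up to 0.31 away from -0.90, the scaled level for 1 of 2 copies lost and the nearer of that level and 0, and lay nearer to -0.53, the scaled level for 1 of 3 copies lost. The chromosome 8 gain was up to 0.26 away from the nearest step. A gain of 5 probes on chromosome 13, from 95703166 to 95712034, was called in both parents and in progeny 1, 2, 3 and 6. Its probe at 95707465 had a mean of 1.65 ± 0.44 (SD) over all progeny and 1.23 over the parents. Whether the gain rested on that single probe was not tested.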
